A study of Arabidopsis thaliana with 24 samples.

How the data were processed

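Whole seedlings of Columbia wild type and of the triple mutant rdr1/2/6 were grown for 2 weeks on MS medium at 22 °C with 16 h light and 8 h dark, and for drought were kept in a plastic dish for 2 h. Per the labels, 100 µg of total RNA was separated with Ambion Poly(A) Purist, the poly(A-) part was depleted of ribosomal RNA with RiboMinus Plant, and 5 ng of poly(A+) or 1.4 µg of poly(A-) RNA was labelled as Cy3 cRNA with the Agilent Low Input Quick Amp kit and put on a custom Agilent array.

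Per the file headers, the intensity values were made by the authors with Agilent Feature Extraction 10.7.3.1 (protocol GE1_107_Sep09), whose processed signal has the background subtracted with spatial and multiplicative detrending. These signals were analysed here. The deposited series matrix holds log2 values with 1 decimal that share one distribution within each fraction, and the authors' notes name RMA and limma without a role or an order for either. They served only as an alternative, and 22 of their 24 columns lay closest to the array of another replicate of the same group, so no block by replicate was fitted to them.

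Of the spots on each array 1319 controls and those marked as non-uniform or population outliers were left out. The other 53459 spots hold 52586 probe names, of which 33121 name an annotated locus and 245 tile the antisense strand of 13 loci. Spots with one probe name were averaged on the log2 scale. Of 32781 probes named by locus 32316 had that locus in the reference gene list (TAIR10.1), which gave symbols and gene types. Probes were compared with each other and 1228 shared 25 nucleotides with a probe of another locus. No genome sequence was used and probes were not mapped again. The chloroplast and mitochondrial gene lists had no probe.

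Signals were taken as log2 and each array's 75th percentile was subtracted. A feature was kept when it lay well above background on every array of at least 1 group, and each target was represented by its brightest kept probe. Groups were taken from the sample titles. Linear models with 1 mean per group and moderated variances with a trend on the mean level (R 4.3.3, limma 3.58.1, data.table (1.17.8), figures with matplotlib 3.10.9) were fitted to the 12 arrays of a fraction, and to all 24 arrays for the 2 comparisons between fractions. P-values were adjusted by the Benjamini-Hochberg method and called under 0.05. The 12 comparisons were drought in each genotype, genotype in each condition and their interaction in each fraction, the fractions as means of their 4 groups, and the difference between fractions of the drought response of wild type. Of 23 gene lists written beforehand 21 had measured members, and were tested with camera (preset correlation 0.01, then an estimated one) and with fry, adjusted over the lists of a comparison. Pseudogenes were compared with protein-coding genes by Fisher's exact test, under 3 filters.

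Genes are named by this rule. RDR1, RDR2 and RDR6 come first in the genotype comparisons. Then follow the 5 largest rises and 5 largest falls among sense features with a locus code that passed and whose groups' values did not overlap, a condition not set for the interactions. Of each list with a called member, in the order of the size of the median, the 2 largest rises and 2 largest falls that passed are taken, up to about 30 genes in a comparison, and the tasiRNA precursors are given in full for drought and genotype. Of the antisense loci the 3 largest rises and falls that passed are given with the sense change. Loci whose probe matches another locus are passed over.

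Sharing of replicate numbers was checked by correlating the arrays' deviations from their group means. The number is the slide by the array names. Same-numbered arrays correlated above 0.1 in all 3 pairs for the 2 wild-type conditions (0.16 to 0.28 in poly(A+) and 0.20 to 0.61 in poly(A-) RNA) and for the 2 genotypes without stress (0.12 to 0.17 and 0.20 to 0.68), so numbers pair the samples in these comparisons. Over all 18 pairs in a fraction 9 in poly(A+) and 13 in poly(A-) RNA passed 0.1. The fit with the replicate as a block called, in the order of the comparisons, 22407, 23189, 1102, 2048 and 65 features in poly(A+) RNA and 3675, 24178, 68, 16987 and 15414 in poly(A-) RNA, and 43789 and 9589 between fractions.

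Tests on simulated data with the arrays' own spread hold only for few changes (67 of 2-fold). In poly(A+) RNA 67.2 to 74.6% of 2-fold changes were recovered in the 4 comparisons of 2 groups and 41.8% in the interaction, with 6 to 10 false calls among 33441 unchanged features. In poly(A-) RNA these were 10.4 to 17.9% and 1.5%, and 65.2 to 80.3% and 16.7% for 4-fold changes. Between fractions 76.1% and, for the drought difference, 19.4% of 2-fold changes were recovered.

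Alternatives fixed before the data were examined were quantile scaling, normexp background correction with an offset of 50, the series matrix values, no filter or a filter on every array, the mean over the probes of a target, the replicate as a fixed or random block, array weights, fits of all 24 or only 6 arrays, and leaving out each array. Alternatives added after the data were seen were slides 2 and 3 alone (slide 1 was scanned on another day), scaling to the array median or to the 75th percentile of spots detected on all arrays, leaving out the 3 poly(A-) arrays whose detection lay over 10 percentage points below the next of their group, removing each poly(A-) array's linear trend on the difference between poly(A+) and poly(A-) levels of unstressed arrays, and testing every antisense probe by itself.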

Results

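The 24 one-colour arrays measured RNA of whole Arabidopsis seedlings in 8 groups, with 3 arrays in each. Wild-type plants (Columbia) were set beside a triple mutant (called rdr1/2/6 here) that carries mutations in RDR1, RDR2 and RDR6, genes of the RNA-dependent RNA polymerases that copy RNA into double-stranded RNA, the source of small interfering RNAs. Both were sampled without stress and after drought, given by 2 h in a plastic dish. Each RNA sample was divided into polyadenylated RNA, poly(A+), and the remaining RNA after removal of ribosomal RNA, poly(A-). The series' design text gives other times for growth and drying than the sample protocols, which were followed here, and groups follow the sample titles because 1 label field gives the opposite genotype for dried wild type and unstressed mutant.

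Each array held 53459 non-control spots for 52586 probe names of 60 nucleotides. These name annotated loci, unannotated transcribed regions, small RNA precursors and, for 13 stress genes, tiled probes for the antisense strand. In poly(A+) RNA 61.2 to 68.7% of the spots lay well above background and replicate arrays correlated at r = 0.987 to 0.994. In poly(A-) RNA the values were 56.3 to 90.9% and r = 0.894 to 0.978, so changes there were measured with less precision. In poly(A-) RNA dried mutant array 3 (62.3% of spots), dried wild-type array 2 (56.3%) and unstressed wild-type array 2 (70.1%), numbered by replicate, lay over 10 percentage points below the next of their group. Each of 3 slides carried 1 array of every group, always at the same place, so position on the slide and group cannot be told apart. Nothing in the labels states that the replicates are separate cultures, so the p-values measure the spread between these samples.

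Changes are log2 differences of group means ± SE with 3 arrays per group, of signals scaled to each array's 75th percentile. Folds are exact where the probe lay well above background in both groups. Where it was dim in 1 group, that group's values were raised to the level of the dimmest probe on the same array that was well above background, which gives the "at least" folds, and no fold is given where both groups were dim. Genes are ranked by the fitted log2 difference, which rests on signal at background where a group was dim, so size and order are not measured there. An adjusted p is printed beside a gene where it was 0.001 or more. Gene lists and comparisons were fixed before the data were examined, and each list's result comes from camera, first with its preset correlation between genes and then with one estimated from the arrays.

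In poly(A+) RNA of wild-type seedlings, the first comparison asked which RNAs differed after drying. Genes of the response to abscisic acid (ABA), the hormone of water deficit, rose together with genes of jasmonate synthesis and signalling and with the clade A PP2C phosphatases, which restrain ABA signalling. Precursors of trans-acting small interfering RNAs (tasiRNAs), which RDR6 copies, fell in 5 of 6 (adjusted p = 0.2 with an estimated correlation). Of 34150 features tested, 21705 passed an adjusted p of 0.05, 9697 of them higher after drying and 12008 lower, and 4274 and 4980 of these had changed at least 2-fold.

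The largest fitted rises were of AT1G78070 (9.86 ± 0.52, at least 455-fold), HSFA6B (AT3G22830, 9.44 ± 0.21, at least 146-fold), AT4G28140 (9.36 ± 0.08, 658-fold), AT5G05220 (9.33 ± 0.20, 644-fold) and DDF1 (AT1G12610, 9.20 ± 1.22, at least 236-fold). The largest fitted falls were of MIR167d (AT1G31173, -6.12 ± 0.27, at least 60.2-fold), a microRNA precursor, AT3G53250 (-5.21 ± 0.37, at least 22.1-fold), AT4G34790 (-5.13 ± 0.30, 34.9-fold), AT5G20790 (-5.10 ± 0.33, 34.2-fold) and XTH12 (AT5G57530, -5.05 ± 0.53, at least 24.2-fold).

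All 31 measured genes of the ABA and dehydration list rose (median 3.46, adjusted p = 6.8e-20, and 0.028 with an estimated correlation). Highest were LEA7 (AT1G52690, 7.09 ± 0.16) and NAC019 (AT1G52890, 6.93 ± 0.14). All 19 jasmonate genes rose (median 3.38, adjusted p = 9e-15 and 0.018). Among them were JAZ5 (AT1G17380, 5.84 ± 0.17) and LOX3 (AT1G17420, 5.62 ± 0.12). All 8 measured PP2C genes of 9 rose (median 2.79, adjusted p = 1.8e-07 and 0.04). HAI1 (AT5G59220, 7.07 ± 0.11) and HAI2 (AT1G07430, 5.48 ± 0.11) rose most. Of 6 tasiRNA precursors 5 fell (median -2.16, adjusted p = 0.0021, and 0.2 with an estimated correlation). They were TAS3 (AT3G17185, -3.23 ± 0.14), TAS1B (AT1G50055, -3.18 ± 0.09), TAS1A (AT2G27400, -2.33 ± 0.11), TAS2 (AT2G39681, -1.99 ± 0.10) and TAS4 (AT3G25795, -0.90 ± 0.15), while TAS1C (AT2G39675, -0.23 ± 0.26, adjusted p = 0.48) was dim.

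Of 18 touch and wound genes 13 rose and 1 fell (median 1.98, adjusted p = 0.0011, and 0.64 with an estimated correlation). CML38 (AT1G76650, 4.90 ± 0.53) and WRKY18 (AT4G31800, 4.83 ± 0.13) rose most and ERF104 (AT5G61600, -1.25 ± 0.46, adjusted p = 0.029) fell. Root markers fell in 9 of 12 (median -1.87, adjusted p = 0.026 and 0.53). WOX5 (AT3G11260, 1.72 ± 0.18) rose. Hypoxia genes, which mark low oxygen, fell in 9 of 10 (median -1.53, adjusted p = 0.0078 and 0.53). The 9 ABA receptor genes gave no list result (2 up, 6 down, median -1.99, adjusted p = 0.11). PYL7 (AT4G01026, 4.33 ± 0.10) and PYL9 (AT1G01360, 1.97 ± 0.11) rose, and PYL6 (AT2G40330, -4.36 ± 0.25) and PYL4 (AT2G38310, -2.95 ± 0.19) fell. The other 13 measured lists did not pass (adjusted p = 0.062 to 0.79).

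The same question in the mutant found nearly the same poly(A+) response, with ABA and jasmonate genes up. Of 34141 features 22496 passed, 10304 up and 12192 down, 4622 and 5319 of them at least 2-fold. Among 19676 features that passed in both genotypes 19649 changed in the same direction and 27 in the opposite one. Over all features tested the log2 changes of the 2 genotypes correlated at r = 0.97 with a slope of 1.01.

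The largest fitted rises were of AT3G53600 (9.76 ± 0.24, at least 227-fold), AT5G05220 (9.52 ± 0.20, at least 736-fold), AT4G28140 (9.49 ± 0.08, 717-fold), AT1G78070 (9.46 ± 0.52, at least 401-fold) and AT4G33467 (9.28 ± 0.15, 621-fold). The largest fitted falls were of AT4G34790 (-6.59 ± 0.30, at least 92.7-fold), MIR167d (-5.89 ± 0.27, at least 51.5-fold), AT5G06490 (-5.81 ± 1.00, at least 19.2-fold), AT3G53250 (-5.70 ± 0.37, at least 44.7-fold) and AT4G38860 (-5.38 ± 0.10, 41.7-fold).

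All 31 ABA genes rose (median 3.58, adjusted p = 9.4e-19, and 0.033 with an estimated correlation), led by LEA4-5 (AT5G06760, 7.48 ± 0.13) and NAC019 (7.43 ± 0.14). All 19 jasmonate genes rose too (median 3.19, adjusted p = 1.5e-13 and 0.024), led by JAZ10 (AT5G13220, 5.65 ± 0.11) and JAZ5 (5.38 ± 0.17). All 8 PP2C genes rose (median 2.65, adjusted p = 6e-07, and 0.05 with an estimated correlation), led by HAI1 (7.06 ± 0.11) and HAI2 (5.51 ± 0.11). Root markers fell in 9 of 12 (median -1.98, adjusted p = 0.01 and 0.45). COBL9 (AT5G49270, -3.64 ± 0.28) and EXPA18 (AT1G62980, -3.48 ± 0.32) fell most and WOX5 (2.57 ± 0.18) rose. Hypoxia genes fell in 8 of 10 (median -1.70, adjusted p = 0.015 and 0.6). PCO2 (AT5G39890, -3.85 ± 0.39) and PCO1 (AT5G15120, -2.78 ± 0.19) fell most, while SUS1 (AT5G20830, 2.11 ± 0.17) rose. TasiRNA precursors fell in 5 of 6 (median -1.46, adjusted p = 0.01 and 0.26). TAS3 (-2.94 ± 0.14), TAS1B (-2.38 ± 0.09), TAS1A (-1.67 ± 0.11), TAS4 (-1.24 ± 0.15) and TAS2 (-0.90 ± 0.10) fell, and TAS1C (0.04 ± 0.26, adjusted p = 0.9) did not pass. Of 18 touch genes 9 rose and 1 fell (median 1.28, adjusted p = 0.015 and 0.71). Of 15 clock genes 10 rose and 4 fell (median 0.42, adjusted p = 0.047 and 0.34). The receptors PYL7 (4.63 ± 0.10) and PYL9 (2.31 ± 0.11) again rose and PYL6 (-4.42 ± 0.25) and PYL4 (-3.23 ± 0.19) fell. Their list did not pass (adjusted p = 0.12), nor did the other 12 lists (adjusted p = 0.061 to 0.99).

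Comparing the mutant with wild type without stress asked which RNAs depend on the 3 polymerases in poly(A+) RNA. RDR2 and RDR6 RNA fell steeply, TAS2 and most tasiRNA target genes rose, and ROS1, a DNA demethylase gene that needs RNA-directed DNA methylation (RdDM) for its expression, fell. Of 34150 features 1011 passed, 555 up and 456 down, 368 and 139 of them at least 2-fold.

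RDR1 (AT1G14790, 0.53 ± 0.39, adjusted p = 0.66) was dim in both groups, while RDR2 (AT4G11130, -7.97 ± 0.68, at least 68.3-fold) and RDR6 (AT3G49500, -5.24 ± 0.24, 37.7-fold) fell. The largest fitted rises were of AT5G27845 (10.29 ± 0.18, at least 332-fold), AT2G01422 (9.12 ± 0.29, 555-fold), AT3G28899 (8.28 ± 0.27, at least 217-fold), AT1G33850 (8.04 ± 0.24, at least 60.7-fold) and AT3G01345 (6.85 ± 0.69, at least 109-fold). Besides RDR2 and RDR6 the largest fitted falls were of ROS1 (AT2G36490, -4.15 ± 0.27, 17.7-fold), WAK5 (AT1G21230, -3.89 ± 0.37, at least 3.62-fold) and AT3G46700 (-3.20 ± 0.27, at least 6.64-fold).

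As a list the 3 targeted genes were lower (0 up, 2 down, median -5.24, adjusted p = 5.8e-05, and 0.024 with an estimated correlation). Of 19 tasiRNA targets 12 rose (14 adjusted within the list, median 0.55, adjusted p = 1.3e-25 and 0.0032). HTT1 (AT4G29770, 2.14 ± 0.13), a target of TAS1 and TAS2 siRNAs, and ARF4 (AT5G60450, 1.71 ± 0.08), an auxin response factor gene targeted by TAS3 siRNAs, rose most. Of the 6 precursors 3 rose (4 within the list, median 0.49, adjusted p = 1.4e-06 and 0.04). They were TAS2 (1.41 ± 0.10, 2.65-fold), TAS3 (0.67 ± 0.14, 1.59-fold, adjusted p = 0.02) and TAS1A (0.63 ± 0.11, 1.54-fold, adjusted p = 0.005). With the replicate as a block TAS1B (0.35 ± 0.09, adjusted p = 0.06) passed too (adjusted p = 0.035). TAS1C (0.12 ± 0.26, adjusted p = 0.92) and TAS4 (0.12 ± 0.15, adjusted p = 0.84) did not pass. Of 3 measured genes that depend on RdDM SDC (AT2G17690, 5.33 ± 0.14) rose and ROS1 fell (list adjusted p = 0.86). Of pseudogenes 82 of 505 (16.2%) were higher and of protein-coding genes 266 of 21892 (1.22%), an odds ratio of 15.8 (95% CI 11.9 to 20.7, Fisher's exact p = 1e-59). It depended on the filter, which lets in a locus silent in wild type only where the mutant raises it. It was 7.74 (4.17 to 13.4) with detection on every array and 2.42 (1.87 to 3.11) without a filter. Transcribed pseudogenes, classed apart, had 17 of 320 higher.

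The remaining list results were lost with an estimated correlation. Auxin and growth genes were higher (4 up, 5 within the list, median 0.62, adjusted p = 2.7e-05 and 0.2). IAA19 (AT3G15540, 0.90 ± 0.16, adjusted p = 0.0066) and ARGOS (AT3G59900, 0.88 ± 0.14, adjusted p = 0.0034) rose most. Flower markers were lower (2 down, 3 within the list, median -0.58, adjusted p = 7.8e-05 and 0.1). AP3 (AT3G54340, -1.61 ± 0.27, adjusted p = 0.0038) and AP1 (AT1G69120, -1.32 ± 0.24, adjusted p = 0.0072) fell, and AG (AT4G18960, -0.39 ± 0.19, adjusted p = 0.4), PI (AT5G20240, -0.27 ± 0.22, adjusted p = 0.69) and SEP3 (AT1G24260, -0.58 ± 0.19, adjusted p = 0.16) did not pass. Touch genes (0 passed, 1 up within the list, median 0.95, adjusted p = 1.7e-06 and 0.4) had slide medians of -0.78, 1.01 and 2.69. ABA genes were lower (2 down, 9 within the list, median -0.25, adjusted p = 6.6e-05 and 0.26). KIN1 (AT5G15960, -0.89 ± 0.15, adjusted p = 0.0043) and LEA4-5 (-0.80 ± 0.13, adjusted p = 0.0024) fell. Salicylic acid and defence genes (0 passed, median 0.27, adjusted p = 0.034 and 0.5) came next. Jasmonate genes were 1 up and 1 down (4 and 1 within the list, median 0.12, adjusted p = 0.04 and 0.4). Hypoxia genes were lower (0 passed, 2 down within the list, median -0.21, adjusted p = 0.026 and 0.51). The other lists did not pass (adjusted p = 0.059 to 0.86). The count of 1011 fell to 659 without unstressed wild-type array 3.

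Under drought the same question again found TAS2, TAS1A, TAS3 and most tasiRNA targets higher and ROS1 lower. Of 34141 features 1703 passed, 964 up and 739 down, 399 and 156 of them at least 2-fold. Of these 601 had also passed without stress, 403 higher in both conditions, 190 lower in both and 8 opposite, where 15.7 and 9.87 shared rises and falls would be expected by chance.

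RDR1 (-0.20 ± 0.39, adjusted p = 0.84) did not differ, and RDR2 (-7.24 ± 0.68, at least 61.4-fold) and RDR6 (-4.49 ± 0.24, 22.4-fold) were lower. Most raised were AT5G27845 (9.33 ± 0.18, at least 165-fold), AT2G01422 (8.00 ± 0.29, 256-fold), AT3G01345 (6.94 ± 0.69, at least 98.9-fold), AT5G24240 (6.75 ± 0.21, 108-fold) and AT1G33850 (6.64 ± 0.24, at least 22.5-fold). Besides RDR2 and RDR6 the largest fitted falls were of ROS1 (-4.25 ± 0.27, 19-fold), AT2G06002 (-2.93 ± 0.23, 7.6-fold) and AT1G48580 (-2.87 ± 0.16, 7.32-fold).

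The targeted genes were lower as a list (0 up, 2 down, median -4.49, adjusted p = 5.9e-05, and 0.021 with an estimated correlation). Of 6 precursors 4 were higher (median 1.05, adjusted p = 8.1e-08 and 0.024). They were TAS2 (2.50 ± 0.10, 5.68-fold), TAS1A (1.28 ± 0.11), TAS1B (1.16 ± 0.09) and TAS3 (0.95 ± 0.14, adjusted p = 0.0015), but not TAS1C (0.39 ± 0.26, adjusted p = 0.46) or TAS4 (-0.22 ± 0.15, adjusted p = 0.48). Of 19 tasiRNA targets 14 were higher and 1 lower (15 and 2 within the list, median 0.75, adjusted p = 6.7e-19 and 0.009). ARF4 (1.44 ± 0.08) and HTT1 (1.43 ± 0.13) were highest and PAP1 (AT1G56650, -0.55 ± 0.10, adjusted p = 0.0055) was lower. SDC (5.60 ± 0.14) was higher. All 5 flower markers were lower within the list and 4 over all features (median -0.95, adjusted p = 5.9e-05, and 0.082 with an estimated correlation). They were AP3 (-1.71 ± 0.27, adjusted p = 0.0022), AP1 (-1.38 ± 0.24, adjusted p = 0.0047), AG (-0.95 ± 0.19, adjusted p = 0.01) and PI (-0.84 ± 0.20, adjusted p = 0.029), with SEP3 (-0.47 ± 0.19, adjusted p = 0.2) the fifth. Jasmonate genes (1 up, 2 within the list, median 0.17, adjusted p = 0.032 and 0.39) passed the preset test alone, with AOC1 (AT3G25760, 0.41 ± 0.09, adjusted p = 0.024) higher. So did clock genes (2 up, 3 within the list, median 0.10, adjusted p = 0.032 and 0.31). No gene of the ABA list passed (median 0.01, adjusted p = 0.95), and the other lists lay at adjusted p = 0.085 to 0.97. Of pseudogenes 94 of 504 (18.7%) were higher and of protein-coding genes 628 of 21889 (2.87%), an odds ratio of 7.76 (95% CI 6.05 to 9.88, Fisher's exact p = 1e-44). It was 3.59 (2.13 to 5.75) with detection on every array and 1.29 (1.02 to 1.61) without a filter. Single calls in lists that did not pass were CASP1 (AT2G36100, -0.83 ± 0.22, adjusted p = 0.047) and LBD41 (AT3G02550, 0.39 ± 0.10, adjusted p = 0.047). The latter call was lost with the replicate as a block (adjusted p = 0.053). The count of 1703 fell to 939 or 1012 without dried wild-type array 1 or 2 and to 1024 without dried mutant array 3.

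**Figure D1:**
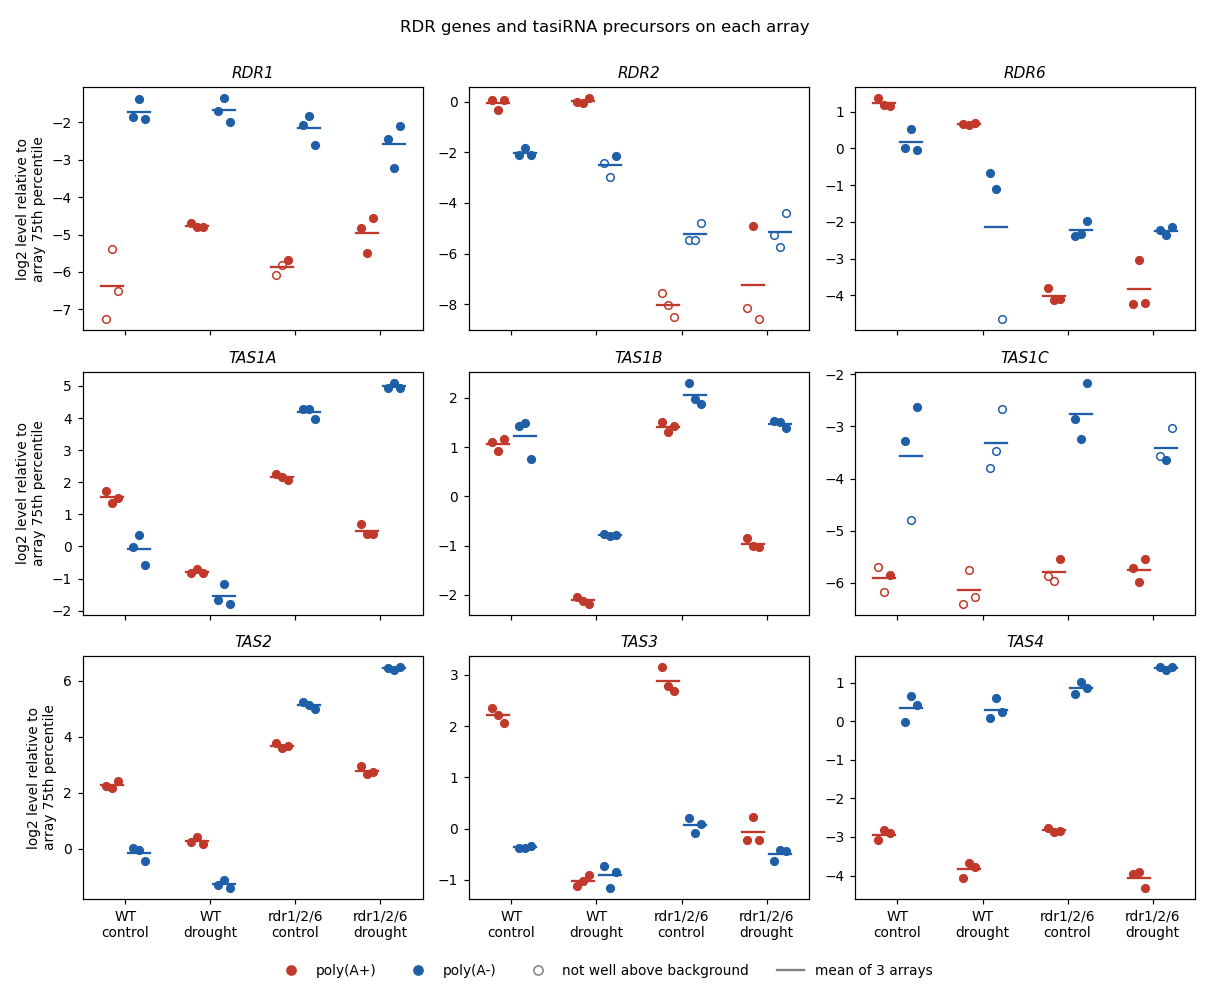
Levels of the 3 targeted genes and 6 tasiRNA precursors on every array, relative to the array's 75th percentile. RDR6 averaged 1.23 in unstressed wild-type poly(A+) RNA and -4.00 in the mutant.

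Whether the mutant's drought response differs from the wild type's was asked as an interaction. In poly(A+) RNA few features passed, and TAS2 and TAS1B, which drought lowered less in the mutant, were among them. Of 34141 features 55 passed, 40 with a higher and 15 with a lower change in the mutant (2442 at a raw p under 0.05).

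The targeted genes did not pass: RDR1 (-0.72 ± 0.56, adjusted p = 0.86), RDR2 (0.73 ± 0.96, adjusted p = 0.92) and RDR6 (0.75 ± 0.34, adjusted p = 0.7). Highest were AT3G43200 (3.14 ± 0.37, adjusted p = 0.0033), AT2G06550 (2.64 ± 0.45, adjusted p = 0.042), AT1G33840 (2.55 ± 0.28, adjusted p = 0.0017, or -0.13 with normexp), AT2G18620 (2.54 ± 0.20) and AT5G16960 (1.93 ± 0.29, adjusted p = 0.021). Lowest were SADHU3-1 (AT3G44042, -3.75 ± 0.18), a retroposon, AT3G28899 (-2.84 ± 0.38, adjusted p = 0.011), AT2G10975 (-2.67 ± 0.39, adjusted p = 0.017), AT1G30190 (-2.23 ± 0.33, adjusted p = 0.021) and AT4G02000 (-2.07 ± 0.34, adjusted p = 0.032). With the replicate as a block AT2G06550 and AT4G02000 no longer passed (adjusted p = 0.055 for each). In the tasiRNA precursor list TAS2 (1.1 ± 0.14, adjusted p = 0.0066) and TAS1B (0.80 ± 0.13, adjusted p = 0.028) passed (2 up, 3 within the list, median 0.47, adjusted p = 0.00015, and 0.29 with an estimated correlation). TAS1A (0.66 ± 0.15, adjusted p = 0.17), TAS1C (0.27 ± 0.37, adjusted p = 0.92), TAS3 (0.28 ± 0.20, adjusted p = 0.85) and TAS4 (-0.34 ± 0.22, adjusted p = 0.83) did not pass. Auxin genes (0 passed, 3 down within the list, median -0.60, adjusted p = 0.00015 and 0.59) were lost with an estimated correlation. So were ABA genes (0 passed, 3 up within the list, median 0.21, adjusted p = 0.0019 and 0.72). Touch genes (0 passed, median -0.49, adjusted p = 0.029 and 0.94) were lost with the replicate as a block too (adjusted p = 0.054). The other lists lay at adjusted p = 0.063 to 0.93. They held ABA3 (AT1G16540, 1.47 ± 0.15, adjusted p = 0.0011), BGLU18 (AT1G52400, -0.64 ± 0.10, adjusted p = 0.021) and AOC1 (0.88 ± 0.13, adjusted p = 0.021). Leaving out 1 array brought the count of 55 to 19 (unstressed mutant array 2), 25 (array 3) and 26 (dried wild-type array 1), and to 33 without unstressed wild-type array 3 or any dried mutant array.

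Drying of wild type raised, in poly(A-) RNA, ABA, jasmonate, PP2C and touch genes, and lowered tasiRNA precursors. Fewer features passed, 2707 of 43215, with 1066 up and 1641 down and 884 and 1241 of them at least 2-fold (7278 at a raw p under 0.05). Scaling to the array median gave 941 up and 904 down, normexp 1042 and 983. Of 2435 features that passed in both fractions 2378 changed in the same direction, 986 up and 1392 down, against 299.6 and 562.2 expected by chance.

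Rising most were AT4G33467 (8.44 ± 0.31, at least 95.9-fold), MAPKKK18 (AT1G05100, 7.49 ± 0.32, at least 175-fold), PUB19 (AT1G60190, 7.36 ± 0.25, 164-fold), CBF1 (AT4G25490, 7.27 ± 0.53, at least 91.1-fold) and HAI1 (7.06 ± 0.33, at least 126-fold). The largest fitted falls were of AT5G20790 (-4.33 ± 0.44, at least 6.11-fold), OFP16 (AT2G32100, -3.99 ± 0.20, 15.9-fold), AT2G36090 (-3.81 ± 0.44, at least 6.4-fold), AT2G44380 (-3.72 ± 0.42, at least 4.21-fold) and SULTR1;2 (AT1G78000, -3.66 ± 0.66, at least 10.8-fold, adjusted p = 0.0037).

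Touch genes rose in 14 of 18 (16 within the list, median 2.77, adjusted p = 2.4e-31, and 0.019 with an estimated correlation). ERF11 (AT1G28370, 5.22 ± 0.40, at least 24.8-fold) and WRKY18 (4.56 ± 0.26) rose most. PP2C genes rose in 6 of 7 (median 2.67, adjusted p = 4.1e-17 and 0.013), with HAI2 (5.31 ± 0.20, at least 31.8-fold). ABA genes rose in 25 of 31 (27 within the list, median 2.50, adjusted p = 4e-48 and 0.0053), led by NAC019 (6.55 ± 0.41, at least 56.5-fold) and LEA4-5 (5.57 ± 0.25). Jasmonate genes rose in 16 of 19 (18 within the list, median 2.35, adjusted p = 1.5e-37 and 0.0053), led by JAZ5 (6.36 ± 0.41, at least 35.8-fold) and LOX3 (5.41 ± 0.25). TasiRNA precursors fell in 3 of 6 (4 within the list, median -0.83, adjusted p = 0.0004 and 0.019). TAS1B (-2.01 ± 0.21, 4.04-fold), TAS1A (-1.46 ± 0.24, 2.75-fold, adjusted p = 0.0021) and TAS2 (-1.12 ± 0.18, 2.17-fold, adjusted p = 0.0018) fell, while TAS3 (-0.55 ± 0.18, adjusted p = 0.098), TAS4 (-0.05 ± 0.21, adjusted p = 0.94) and TAS1C (0.25 ± 0.51, adjusted p = 0.86) did not pass.

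Lost with an estimated correlation were ABA receptors (1 up and 4 down, 2 and 5 within the list, median -1.74, adjusted p = 0.0051 and 0.37). PYL9 (1.21 ± 0.32, 2.32-fold, adjusted p = 0.038) rose and PYL6 (-2.62 ± 0.30) and PYL5 (AT5G05440, -1.90 ± 0.35, at least 3.74-fold, adjusted p = 0.004) fell. Root markers were lost too (3 down of 10, 6 within the list, median -1.35, adjusted p = 0.0025 and 0.15), with EXPA7 (AT1G12560, -2.14 ± 0.39, at least 2.08-fold, adjusted p = 0.0041) and EXPA18 (-1.53 ± 0.38, no fold, adjusted p = 0.027) lowest. So were hypoxia genes (5 down of 10, 8 within the list, median -1.02, adjusted p = 2e-05 and 0.15), with PCO1 (-1.99 ± 0.35, at least 3.7-fold, adjusted p = 0.0029) and HRE2 (AT2G47520, -1.78 ± 0.33, no fold, adjusted p = 0.0049), and auxin genes (3 up and 2 down, 4 up and 2 down within the list, median 0.32, adjusted p = 0.036 and 0.38, and 0.054 with the replicate as a block). Elsewhere lists lay at adjusted p = 0.073 to 0.99. The count of 2707 fell to 1663 or 1685 without unstressed or dried wild-type array 1.

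In the mutant's poly(A-) RNA ABA and jasmonate genes rose. Regions were 91 up and 2910 down of 5008 and pseudogenes 57 and 953 of 2470, but 455 and 575 and 262 and 132 with a trend described under the interaction removed. Of 43177 features 20945 passed, 7455 up and 13490 down, 4203 and 7832 of them at least 2-fold, with a median over all features of -0.35. These splits depended on scaling: array median scaling gave 10185 up and 7466 down with a median of -0.01, the 75th percentile of detected spots 5567 and 18346 with -0.60, and removal of the trend 6242 and 7407. Of 1616 features that passed in both genotypes 1599 changed in the same direction. Over all features tested, called or not, the log2 changes correlated at r = 0.49 with a slope of 0.79. The median size over all features was 0.27 in wild type and 0.69 in the mutant. Of 9534 that passed in both fractions of the mutant 2559 changed in opposite directions, and 3880 rose and 3095 fell in both (2226.4 and 2372.2 expected by chance).

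Most raised were MAPKKK18 (8.95 ± 0.32, at least 454-fold), PUB19 (8.71 ± 0.25, 419-fold), AT4G33467 (8.63 ± 0.31, at least 213-fold), NAC019 (8.49 ± 0.41, at least 189-fold) and CYP94B1 (AT5G63450, 8.43 ± 0.56, at least 75.9-fold). The largest fitted falls were of AT1G01115 (-3.37 ± 0.45, at least 5.13-fold), AT1G20405 (-3.12 ± 0.39, at least 7.03-fold), AT3G40640 (-3.11 ± 0.36, at least 3.52-fold), AT1G06990 (-3.09 ± 0.46, at least 3.91-fold) and AT5G07490 (-2.99 ± 0.41, at least 3.26-fold).

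PP2C genes rose in 7 of 7 (median 4.03, adjusted p = 9.8e-11, and 0.053 with an estimated correlation), led by HAI1 (8.15 ± 0.33, at least 271-fold) and HAI2 (5.75 ± 0.20). Touch genes rose in 17 of 18 (median 3.94, adjusted p = 4.7e-19 and 0.087), with WRKY18 (6.39 ± 0.26) and ERF11 (5.36 ± 0.40, at least 41.1-fold). ABA genes rose in 28 of 31 (29 within the list, median 3.36, adjusted p = 2.9e-28 and 0.03), led by LEA4-5 (7.5 ± 0.25). Jasmonate genes rose in 17 of 19 (median 3.20, adjusted p = 1.4e-20 and 0.03), with JAZ5 (7.80 ± 0.41, at least 80.4-fold) and LOX3 (6.47 ± 0.25). Of the ABA metabolism genes 6 rose and 1 fell (7 and 1 within the list, median 1.09, adjusted p = 9.9e-05 and 0.15). The synthesis gene NCED3 (AT3G14440, 4.32 ± 0.29) and the catabolism gene CYP707A3 (AT5G45340, 1.88 ± 0.24) rose and CYP707A4 (AT3G19270, -1.72 ± 0.42, at least 2.25-fold, adjusted p = 0.0053) fell. Photosynthesis genes (15 up and 1 down of 21, median 0.95, adjusted p = 1.7e-05 and 0.37) were lost with an estimated correlation. LHCB1.2 (AT1G29910, 2.34 ± 0.32) and LHCB5 (AT4G10340, 1.89 ± 0.39, adjusted p = 0.002) rose most and LHCB2.2 (AT2G05070, -1.31 ± 0.24, at least 2.33-fold) fell. Clock genes were lost too (8 up, 2 down, median 0.82, adjusted p = 0.0008 and 0.37), with FKF1 (AT1G68050, 3.21 ± 0.23) and PRR5 (AT5G24470, 3.08 ± 0.17) up and RVE8 (AT3G09600, -1.70 ± 0.40, at least 1.6-fold, adjusted p = 0.0041) down. So were 9 reference transcripts (4 up and 1 down, 5 and 1 within the list, median 0.74, adjusted p = 0.0097 and 0.37). The same holds for auxin genes (5 up, 1 down, median 0.59, adjusted p = 0.0039 and 0.31) and 23 RNA silencing genes (6 up and 1 down, 6 and 0 within the list, median 0.36, adjusted p = 0.013 and 0.31). Remaining lists lay at adjusted p = 0.33 to 0.98. Of the root markers TIP2.3 (AT5G47450, 1.00 ± 0.24, adjusted p = 0.0053) and PHO1 (AT3G23430, 0.88 ± 0.25, adjusted p = 0.011) rose and EXPA7 (-2.23 ± 0.39, at least 2.84-fold) and COBL9 (-1.87 ± 0.42, at least 2.16-fold, adjusted p = 0.0032) fell (list adjusted p = 0.44). Of the 6 precursors (median -0.03, mean 0.14, 3 up and 2 down within the list) TAS2 (1.32 ± 0.18, 2.5-fold) and TAS1A (0.80 ± 0.24, 1.74-fold, adjusted p = 0.016) rose, where both fell in wild type, TAS3 (-0.57 ± 0.18, adjusted p = 0.019) and TAS1B (-0.58 ± 0.21, adjusted p = 0.035) fell, and TAS4 (0.51 ± 0.21, adjusted p = 0.056) and TAS1C (-0.65 ± 0.51, adjusted p = 0.3) did not pass.

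Without stress, the mutant's poly(A-) RNA differed from wild type in few features. TAS2 and TAS1A rose more than in poly(A+) RNA, ARF4 rose and ROS1 fell. Of 43214 features 50 passed, 44 up and 6 down (1102 with array weights, 4242 at a raw p under 0.05). Of 31 that also passed in poly(A+) RNA 30 went the same way.

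RDR1 (-0.45 ± 0.32, adjusted p = 0.6) did not differ, RDR2 (-3.23 ± 0.40, at least 3.55-fold, adjusted p = 0.0036) fell, and RDR6 (-2.39 ± 0.72, adjusted p = 0.47) did not pass, though all 3 mutant arrays (-2.38 to -1.98) lay below wild type (-0.05 to 0.52). Its SE holds the spread of dried wild type (SD 2.19). Highest above wild type were TAS2 (5.28 ± 0.18, 38.9-fold), TAS1A (4.26 ± 0.24, 19.2-fold), AT2G01422 (3.12 ± 0.20, 8.7-fold), the retroposon SADHU3-2 (AT3G42658, 3.09 ± 0.23, 8.51-fold) and AT1G36675 (2.83 ± 0.38, at least 3.88-fold, adjusted p = 0.0072). Besides RDR2 the largest fitted falls were of ROS1 (-3.20 ± 0.22, 9.21-fold), AT1G52000 (-2.02 ± 0.28, 4.05-fold, adjusted p = 0.0081), AT1G47400 (-1.52 ± 0.25, 2.88-fold, adjusted p = 0.033) and AT1G47395 (-1.46 ± 0.22, 2.76-fold, adjusted p = 0.02).

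The targeted genes were lower (0 up and 1 down, 2 down within the list, median -2.39, adjusted p = 3.7e-05, and 0.031 with an estimated correlation). Precursors were higher (2 up, 5 within the list, median 0.82, adjusted p = 2.1e-11 and 0.0017). TAS1B (0.82 ± 0.21, adjusted p = 0.38), TAS1C (0.81 ± 0.51, adjusted p = 0.56), TAS3 (0.44 ± 0.18, adjusted p = 0.5) and TAS4 (0.52 ± 0.21, adjusted p = 0.5) did not pass over all features. Of the tasiRNA targets 2 rose (5 within the list, median 0.35, adjusted p = 2.4e-05, and 0.3 with an estimated correlation), the auxin response factor genes ARF4 (2.78 ± 0.22, 6.89-fold) and ARF3 (AT2G33860, 1.81 ± 0.28, 3.52-fold, adjusted p = 0.02). No gene passed in the hypoxia (median -0.34, adjusted p = 0.0081 and 0.67) and ABA lists (median -0.22, adjusted p = 0.0036 and 0.67), both lost with an estimated correlation. So were RNA silencing (median -0.19, adjusted p = 0.0046 and 0.3) and photosynthesis genes (median -0.16, or 0.08 with the trend removed, adjusted p = 0.013 and 0.67). The other lists lay at adjusted p = 0.052 to 0.96. With the replicate as a block the PP2C (0.052 to 0.031) and ABA receptor lists (0.064 to 0.046) passed. SDC (0.68 ± 0.20, adjusted p = 0.46), FWA (AT4G25530, 0.72 ± 0.50, adjusted p = 0.59) and EPF2 (AT1G34245, -0.05 ± 0.23, adjusted p = 0.94), loci silenced by RdDM, did not pass. Without 1 of the unstressed mutant arrays 25, 25 and 26 features passed.

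Under drought the mutant's poly(A-) RNA differed from wild type in many more features, with protein-coding genes mostly higher and unannotated regions mostly lower. TasiRNA precursors again rose most. Of 43177 features 12050 passed, 6510 up and 5540 down, 1832 and 2357 of them at least 2-fold. The count fell to 1994 or 2850 without dried mutant array 2 or 3 and to 3691 or 5257 without dried wild-type array 1 or 3. It was 16920 without dried mutant array 1, and array median scaling gave 8557 up and 3482 down, the 75th percentile of detected spots 4220 and 7594. Protein-coding genes were 6093 up and 1805 down, unannotated regions 49 and 1276, pseudogenes 18 and 294, which turned to 547 and 511, 122 and 48, and 46 and 8 with the trend removed. Of 531 features that also passed in poly(A+) RNA 384 rose and 54 fell in both, against 186.6 and 52.3 expected by chance.

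RDR1 (-0.91 ± 0.32, 1.87-fold, adjusted p = 0.048) and RDR2 (-2.63 ± 0.40, no fold, adjusted p = 0.0033) were lower, the latter dim in both groups, and RDR6 (-0.10 ± 0.72, adjusted p = 0.92) did not pass. Dried wild-type array 3, not detected, lay at -4.65 and arrays 1 and 2 at -0.66 and -1.1, against -2.36 to -2.14 in the mutant. Highest above wild type were TAS2 (7.72 ± 0.18, 211-fold), TAS1A (6.52 ± 0.24, 91.8-fold), SADHU3-2 (4.64 ± 0.23, at least 21.7-fold), RAV2 (AT1G68840, 3.93 ± 1.39, at least 10.3-fold, adjusted p = 0.049) and AT1G22810 (3.85 ± 0.75, at least 8.74-fold, adjusted p = 0.0076). The largest fitted falls were of AT3G30844 (-3.19 ± 0.54, at least 5.79-fold, adjusted p = 0.0046), MYB50 (AT1G57560, -2.90 ± 0.45, 7.48-fold, adjusted p = 0.0033), AT5G49600 (-2.88 ± 0.43, 7.37-fold, adjusted p = 0.0029), ROS1 (-2.83 ± 0.22, 7.09-fold) and AT5G59170 (-2.75 ± 0.49, no fold, adjusted p = 0.0057).

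Precursors were higher in 4 of 6 (5 within the list, median 1.66, adjusted p = 6.2e-07, and 0.012 with an estimated correlation). They were TAS2, TAS1A, TAS1B (2.26 ± 0.21, 4.78-fold) and TAS4 (1.07 ± 0.21, 2.1-fold, adjusted p = 0.0072), not TAS3 (0.42 ± 0.18, adjusted p = 0.085) or TAS1C (-0.09 ± 0.51, adjusted p = 0.9). Every other list that passed was lost with an estimated correlation, at adjusted p = 0.26 for all but the tasiRNA targets. They were touch genes (16 up, 17 within the list, median 1.17, adjusted p = 2.2e-07), with ERF11 (1.47 ± 0.40, adjusted p = 0.023) and ZAT10 (AT1G27730, 1.46 ± 0.36, adjusted p = 0.017), and jasmonate genes (12 and 15 up, median 0.90, adjusted p = 6.2e-07), with AOC1 (1.22 ± 0.23, adjusted p = 0.0064) and AOC2 (AT3G25770, 1.19 ± 0.29, adjusted p = 0.016). ABA receptors were higher (4 and 6 up, median 0.87, adjusted p = 0.0046), with PYL5 (1.40 ± 0.35, at least 2.64-fold, adjusted p = 0.017) and PYL9 (1.05 ± 0.32, adjusted p = 0.031). PP2C genes followed (4 and 7 up, median 0.84, adjusted p = 0.0016), with PP2CA (AT3G11410, 1.01 ± 0.31, adjusted p = 0.031) and HAI1 (0.93 ± 0.33, 1.9-fold, adjusted p = 0.049). ABA genes were higher (19 up, 25 up and 1 down within the list, median 0.82, adjusted p = 3.7e-08), with NAC019 (1.38 ± 0.41, adjusted p = 0.029) and LTI30 (AT3G50970, 1.27 ± 0.21, adjusted p = 0.0043). Clock genes were mostly higher (7 up and 1 down, 10 and 1 within the list, median 0.79, adjusted p = 0.00071), with FKF1 (1.17 ± 0.23, adjusted p = 0.0077) and ELF4 (AT2G40080, 1.09 ± 0.28, at least 1.92-fold, adjusted p = 0.019) up and LHY (AT1G01060, -0.77 ± 0.16, adjusted p = 0.01) down. Auxin (4 and 6 up, median 0.70, adjusted p = 0.0027), ABA metabolism (7 up and 1 down, 9 and 1 within the list, median 0.69, adjusted p = 0.00071) and reference genes (4 up, median 0.63, adjusted p = 0.0046) were higher. So were photosynthesis (5 and 4 up, median 0.62, adjusted p = 8.7e-05) and RNA silencing genes (8 and 9 up, median 0.26, adjusted p = 0.0046). The tasiRNA targets were 6 up and 3 down (8 and 3 within the list, median 0.23, adjusted p = 0.026, and 0.36 with an estimated correlation). Elsewhere lists lay at adjusted p = 0.1 to 0.83. With the trend removed 13 of the 30 values named for this comparison lost their call, RDR1 and the touch, ABA, ABA receptor and PP2C genes named among them.

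For the interaction in poly(A-) RNA protein-coding genes passed mostly with higher changes in the mutant (4464 up, 931 down) and regions with lower ones (10 and 939), but the count rested on single arrays. Of 43177 features 7872 passed, 4576 up and 3296 down, and the count ran from 0 without dried wild-type array 1 to 15650 without dried mutant array 1. It was 0 in the submitters' scaling, 15414 with the replicate as a block, 6275 up and 996 down with array median scaling and 3080 and 6436 with the 75th percentile of detected spots. In the dried mutant, RNAs that were stronger in poly(A+) than in poly(A-) RNA stood higher in poly(A-) RNA (mean slope 0.13 per log2 unit of that difference, against 0.03, -0.01 and -0.03 in the other 3 groups; its arrays lay at 0.07, 0.21 and 0.13, the first below unstressed wild-type array 2 at 0.08), and with this trend removed from each array 1 feature passed, TAS2 (2.1 ± 0.21, adjusted p = 0.013).

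For genes of this comparison without a printed p, the adjusted p was 0.041. RDR1 (-0.46 ± 0.45, adjusted p = 0.43), RDR2 (0.60 ± 0.57, adjusted p = 0.42) and RDR6 (2.29 ± 1.02, adjusted p = 0.11), which rests on the same dried wild-type array 3, did not pass. Highest were AT1G22810 (3.75 ± 1.06), AT1G62330 (3.52 ± 0.82), AT5G62360 (3.36 ± 0.84), AT1G50040 (2.83 ± 0.72) and CYP94B1 (2.79 ± 0.80). Lowest were AT1G01115 (-2.99 ± 0.64), AT5G59170 (-2.87 ± 0.70), AT1G35625 (-2.85 ± 0.71), RALFL25 (AT3G25165, -2.77 ± 0.77) and AT3G40640 (-2.69 ± 0.51). Of the precursors TAS2 (2.44 ± 0.26, adjusted p = 0.011), TAS1A (2.26 ± 0.34) and TAS1B (1.43 ± 0.29) passed (median 0.99, list adjusted p = 0.003, and 0.24 with an estimated correlation). With the trend removed TAS1A (2.06 ± 0.31) and TAS1B (1.27 ± 0.26) had an adjusted p of 0.13. TAS1C (-0.90 ± 0.72, adjusted p = 0.34), TAS3 (-0.02 ± 0.25, adjusted p = 0.96) and TAS4 (0.55 ± 0.29, adjusted p = 0.16) did not pass.

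No list kept its result with an estimated correlation. Higher with the preset one were PP2C genes (4 up, 5 within the list, median 1.36, adjusted p = 0.0009 and 0.32), with ABI1 (AT4G26080, 1.69 ± 0.44) and PP2CA (1.46 ± 0.44, adjusted p = 0.043). ABA receptors (3 and 4 up, median 1.2, adjusted p = 0.0027 and 0.33) held PYL5 (1.81 ± 0.49) and PYL1 (AT5G46790, 1.38 ± 0.38). Reference transcripts were mixed (3 up and 1 down, 7 and 1 within the list, median 1.08, adjusted p = 0.0046 and 0.33), with YLS8 (AT5G08290, 1.28 ± 0.40, adjusted p = 0.044, or -0.06 with the trend removed) and UBC21 (AT5G25760, 1.08 ± 0.34, adjusted p = 0.045) up and TIP41L (AT4G34270, -1.32 ± 0.42, adjusted p = 0.047) down. Touch genes were higher (3 and 7 up, median 1.04, adjusted p = 3.7e-05 and 0.33), with WRKY18 (1.83 ± 0.36) and TCH4 (AT5G57560, 1.66 ± 0.48). ABA genes were too (12 and 17 up, median 1.01, adjusted p = 2.7e-08 and 0.3), with NAC019 (1.94 ± 0.58, adjusted p = 0.043) and LEA4-5 (1.93 ± 0.35). Photosynthesis (5 up, median 0.98, adjusted p = 3.7e-05 and 0.33) and jasmonate genes (7 and 8 up, median 0.94, adjusted p = 2.8e-05 and 0.3) followed. So did ABA metabolism (1 up, 7 up and 1 down within the list, median 0.92, adjusted p = 0.0015 and 0.3) and clock genes (5 up and 1 down, 9 and 1 within the list, median 0.88, adjusted p = 0.00089 and 0.33). Last came hypoxia (1 up, 0 within the list, median 0.74, adjusted p = 0.025 and 0.41), RNA silencing (6 and 8 up, median 0.69, adjusted p = 0.00089 and 0.3) and auxin genes (0 passed, median 0.68, or -0.14 with the trend removed, adjusted p = 0.022 and 0.33). Remaining lists lay at adjusted p = 0.19 to 0.83.

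Antisense RNA of 13 stress genes, the series' subject, was tested by the same model, with 1 probe per locus, another in each fraction. In poly(A+) RNA 10 of 13 passed in wild type, 6 up and 4 down, each in the direction of its sense RNA. RD29A antisense (6.32 ± 0.20), DREB2A antisense (5.26 ± 0.22) and NCED3 antisense (4.83 ± 0.13) rose most, beside sense changes of 5.57 ± 0.18, 5.67 ± 0.24 and 4.90 ± 0.10. HSFA7A antisense (-0.96 ± 0.23, adjusted p = 0.0022), HSP81-3 antisense (-0.85 ± 0.12) and HSP90.1 antisense (-0.66 ± 0.21, adjusted p = 0.016) fell most, beside -1.17, -0.83 and -0.89. HSFA3 antisense (0.39 ± 0.39, adjusted p = 0.4) did not pass beside a sense rise of 2.33, but 11 of its 12 antisense probes rose when each was tested. In the mutant 11 passed, 6 up and 5 down, with changes of 6.68, 4.96 and 4.22 for the same 3 drought loci (sense 5.90, 5.65 and 4.66) and of -1.42, -0.91 and -0.82 for the same 3 heat shock loci (sense -1.50, -0.92 and -1.17).

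**Figure D2:**
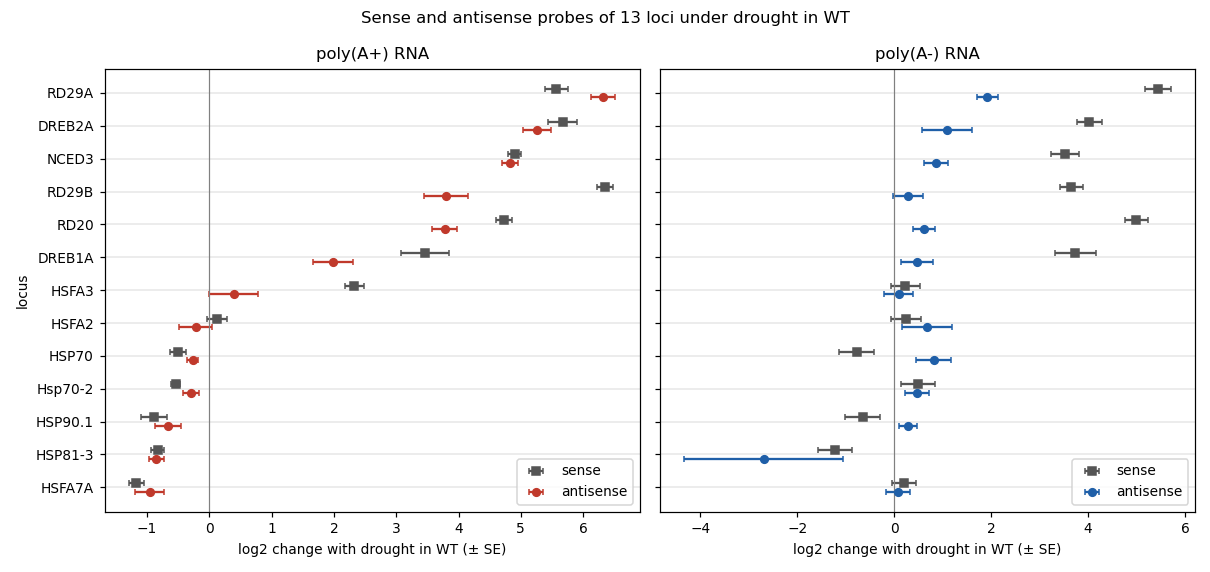
Drought changes of sense and antisense probes in wild type. RD29A antisense changed by 6.32 in poly(A+) and by 1.92 in poly(A-) RNA.

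Between the genotypes no locus of the 13 passed in poly(A+) RNA: limma called 0 without stress (2 at a raw p under 0.05), 0 under drought (1) and 0 in the interaction (1). Over all 197 antisense probes tested, 120 rose and 42 fell with drought in wild type and 121 and 49 in the mutant, while 1 fell in the mutant in each condition. Drying raised 1 of 13 in poly(A-) RNA of wild type (4 at a raw p under 0.05, and 4 called with the replicate as a block), RD29A by 1.92 ± 0.22 (sense 5.44), but 49 of 197 probes, 20 of 25 for RD20, 20 of 23 for RD29A and 5 of 10 for NCED3, and lowered none. It changed 3 in the mutant, RD29A (1.95, sense 6.98) and Hsp70-2 (0.82, sense 0.52) up and HSP90.1 (-0.56, sense -0.36) down, or 4 up and 0 down with the trend removed. Of the probes 58 rose and 34 fell there, or 72 and 15 with the trend removed. The mutant differed in 0 loci without stress (1 at a raw p under 0.05), in 1 under drought (3, and 2 called with the block), HSP90.1 antisense (-0.80 ± 0.21, adjusted p = 0.022) with sense 0.04 ± 0.36, and in 0 in the interaction (1, and 1 called with the block). Of the 197 probes 1 was higher and 24 lower under drought and 0 and 17 in the interaction, or 1 and 2 and 0 and 0 with the trend removed, which also lost the call of HSP90.1, while array median scaling called 1 locus up and 0 down.

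Comparing the fractions, as means of 4 groups each, asked which RNAs lack a poly(A) tail. Unannotated regions (4932 up and 131 down of 5111) and snoRNAs and snRNAs (149 and 1 of 151) stood higher in poly(A-) RNA. Of 46379 features 43628 passed, 27358 higher in poly(A-) RNA and 16270 lower. Amounts labelled differ between fractions and the split followed the scaling. The median over all features was 1.2, and -0.88 with array median scaling (19242 up, 25304 down), 2.14 with detected spots (32645 and 10931) and -0.15 with quantile scaling (19906 and 22093).

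Highest were AT1G39670 (13.27 ± 0.10), AT2G07731 (12.06 ± 0.12), AT4G08345 (12.03 ± 0.22), AT1G38790 (11.96 ± 0.28) and AT2G16540 (11.54 ± 0.17). Lowest were LTP2 (AT2G38530, -7.14 ± 0.10), AT3G16670 (-6.72 ± 0.11), AT5G24620 (-6.59 ± 0.08), EBP (AT3G16770, -6.43 ± 0.11) and PRA1.B4 (AT2G38360, -6.37 ± 0.18). Flower markers were 4 up and 0 down (median 2.01, adjusted p = 0.59). They were PI (2.87 ± 0.13), AG (2.29 ± 0.12), AP3 (2.01 ± 0.15) and SEP3 (0.86 ± 0.13), of which AG, AP3 and SEP3 reversed with other scalings, and AP1 (-0.22 ± 0.14, adjusted p = 0.15). Lists that passed were all lost with an estimated correlation (adjusted p = 0.44 to 0.57). ABA genes were 4 up and 25 down (median -1.66, adjusted p = 3.3e-05), KIN1 (1.60 ± 0.10) and ERD10 (AT1G20450, 0.84 ± 0.13) (-0.49 and -1.24 with array median scaling) against LTI30 (-4.39 ± 0.08) and GOLS1 (AT2G47180, -4.09 ± 0.08). Jasmonate genes were 2 up and 15 down (median -1.50, adjusted p = 0.00046), JAZ8 (AT1G30135, 2.76 ± 0.12) and JAZ6 (AT1G72450, 1.42 ± 0.11) (the latter -0.67 with array median scaling) against VSP2 (AT5G24770, -5.06 ± 0.10) and VSP1 (AT5G24780, -4.96 ± 0.09). Photosynthesis genes were 1 up and 19 down (median -1.45, adjusted p = 3.3e-05), CA1 (AT3G01500, 0.48 ± 0.15, adjusted p = 0.0044) (reversed with 2 scalings) against LHCA2 (AT3G61470, -3.67 ± 0.08) and RBCS2B (AT5G38420, -3.62 ± 0.10). Clock genes (4 and 10, median -1.13, adjusted p = 0.02), ABA receptors (1 and 8, median -1.03, adjusted p = 0.029) and reference transcripts (2 and 7, median -0.89, adjusted p = 0.033) were lower too. So were touch (4 and 11, median -0.79, adjusted p = 0.029), auxin (1 and 7, median -0.70, adjusted p = 0.032) and RNA silencing genes (6 and 13, median -0.45, adjusted p = 0.029). With scaling to detected spots the last 4 had medians of 0.04, 0.14, 0.23 and 0.48. The other lists lay at adjusted p = 0.072 to 0.93. All 13 antisense loci passed, 10 higher in poly(A-) RNA, most HSP90.1 antisense (5.45 ± 0.14), HSFA7A antisense (4.56 ± 0.12) and HSFA2 antisense (3.68 ± 0.21), beside sense differences of -0.64, 0.72 and 4.09. The 3 lower were Hsp70-2 antisense (-1.04 ± 0.10), RD29A antisense (-0.47 ± 0.13, adjusted p = 0.0019) and HSP70 antisense (-0.18 ± 0.07, adjusted p = 0.016), beside 0.56, -1.69 and -0.77.

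The last comparison asked whether drought changed the 2 fractions of wild type differently. TasiRNA precursors fell less in poly(A-) RNA, 3 of them not so under quantile scaling, and antisense RNA of 5 drought loci and sense RNA of 3 of these rose less. Of 46426 features 8662 passed, 4213 up and 4449 down (13738 at a raw p under 0.05).

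Highest were AT2G27420 (5.52 ± 0.60), AT1G53620 (5.44 ± 0.72), AT2G27395 (5.23 ± 0.46), ZIP9 (AT4G33020, 5.18 ± 0.68) and AT5G67430 (5.18 ± 0.90). Lowest were HSFA6B (-8.21 ± 0.32), ddf2 (AT1G63030, -7.86 ± 0.91), AT1G70130 (-7.47 ± 0.39), ILL5 (AT1G51780, -7.28 ± 0.58) and AT3G56790 (-7.13 ± 0.55), all dim in unstressed poly(A+) RNA, as AT1G53620, ZIP9 and AT5G67430 were in dried. Precursors passed in 5 of 6 (median 0.87, adjusted p = 0.00019, and 0.012 with an estimated correlation). They were TAS3 (2.68 ± 0.22), TAS1B (1.17 ± 0.22), TAS1A (0.87 ± 0.27, adjusted p = 0.023), TAS2 (0.87 ± 0.19, adjusted p = 0.0019) and TAS4 (0.85 ± 0.26, adjusted p = 0.022), but not TAS1C (0.48 ± 0.59, adjusted p = 0.66). TAS1B, TAS1A and TAS2 reversed with quantile scaling. The other results were lost with an estimated correlation. ABA metabolism genes were 1 up and 5 down (2 and 6 within the list, median -1.04, adjusted p = 0.014 and 0.46), CYP707A4 (1.79 ± 0.50, adjusted p = 0.014) against NCED5 (AT1G30100, -2.89 ± 0.43) and NCED9 (AT1G78390, -2.84 ± 0.37). ABA genes were 13 down (17 within the list, median -0.76, adjusted p = 5.1e-06 and 0.46), lowest LEA7 (-5.22 ± 0.35) and MYB2 (AT2G47190, -2.75 ± 0.64, adjusted p = 0.0037). Touch genes were 1 up (median 0.68, adjusted p = 0.043 and 0.69, and 0.053 with the replicate as a block), TCH4 (2.1 ± 0.46, adjusted p = 0.0023). Auxin genes were 3 up (median 0.58, adjusted p = 0.031 and 0.57), with EXPA8 (AT2G40610, 1.79 ± 0.36) and PRE1 (AT5G39860, 1.52 ± 0.28), and photosynthesis genes 6 up (median 0.38, adjusted p = 0.031 and 0.69). Jasmonate genes were 1 up and 6 down (1 and 8 within the list, median -0.50, adjusted p = 0.0018 and 0.48), and 7 up and 1 down with a median of 0.62 under quantile scaling. Elsewhere lists lay at adjusted p = 0.1 to 0.91. Antisense loci passed in 5 of 13, all down, led by DREB2A antisense (-3.98 ± 0.37), RD29A antisense (-3.52 ± 0.39) and RD29B antisense (-2.86 ± 0.48), beside sense differences of -2.74, -0.14 (adjusted p = 0.84) and -1.78. For lists that passed, within-list counts differ only where both are given.

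**Figure D3:**
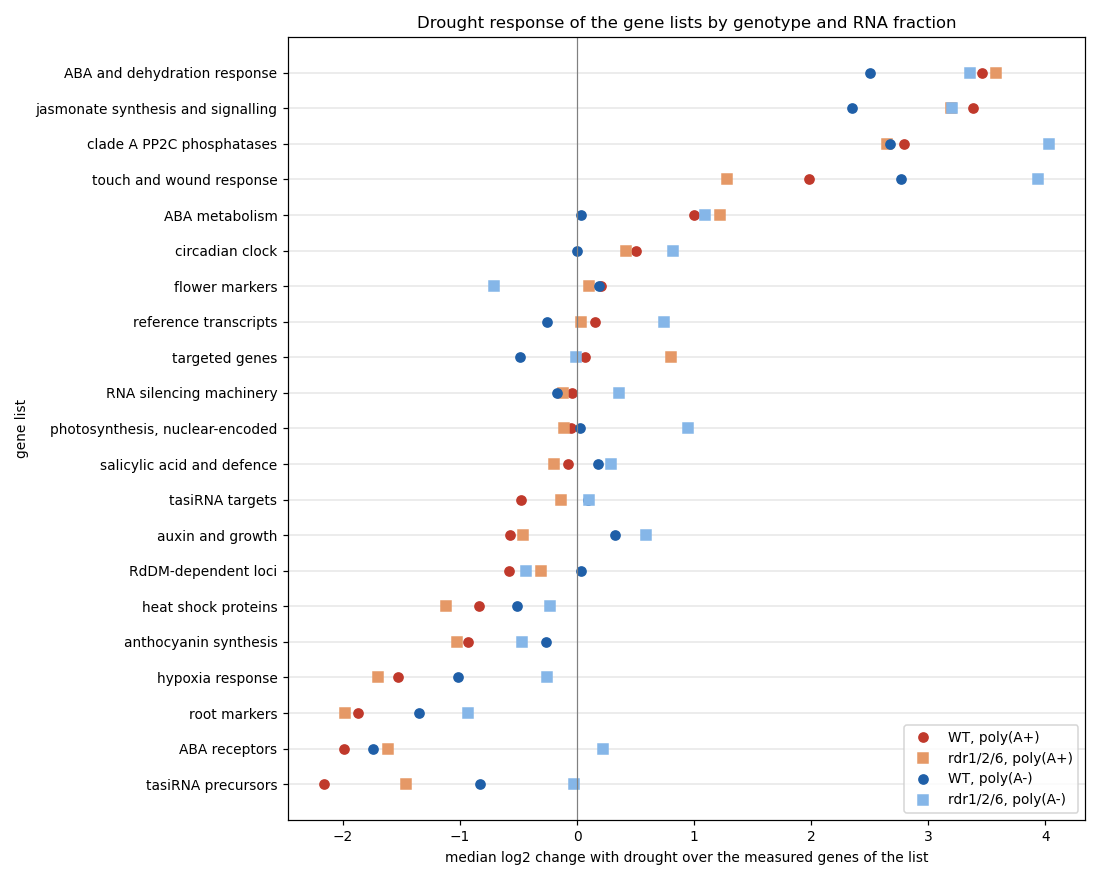
Median drought change of each gene list in both genotypes and fractions. The ABA list had medians of 3.46 and 3.58 in poly(A+) RNA and 2.50 and 3.36 in poly(A-) RNA.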

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

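The tests of messenger RNA share, antisense probes and pseudogenes under other filters and the fit without 3 low-detection arrays were chosen after the results were seen. Quantile scaling as a setting, shared signal, linkage and other splits of the arrays were set beforehand.

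The difference between the genotypes' drought responses was tested as an interaction. In poly(A+) RNA 55 features passed, among them AT3G43200 (3.14), AT2G06550 (2.64), AT1G33840 (2.55), AT2G18620 (2.54), AT5G16960 (1.93), SADHU3-1 (-3.75), AT3G28899 (-2.84), AT2G10975 (-2.67), AT1G30190 (-2.23), AT4G02000 (-2.07), TAS2 (1.1) and TAS1B (0.80). In poly(A-) RNA 7872 passed, among them AT1G22810 (3.75), AT1G62330 (3.52), AT5G62360 (3.36), AT1G50040 (2.83), CYP94B1 (2.79), AT1G01115 (-2.99), AT5G59170 (-2.87), AT1G35625 (-2.85), RALFL25 (-2.77), AT3G40640 (-2.69), TAS2 (2.44), TAS1A (2.26) and TAS1B (1.43). Each of the 12 fits that left out 1 array moved the latter count by over 1.5 times, from 0 without dried wild-type array 1 to 15650 without dried mutant array 1. The drought responses of the 2 fractions of wild type differed in 8662 features, among them AT2G27420 (5.52), AT1G53620 (5.44), AT2G27395 (5.23), ZIP9 (5.18), AT5G67430 (5.18), HSFA6B (-8.21), ddf2 (-7.86), AT1G70130 (-7.47), ILL5 (-7.28), AT3G56790 (-7.13), TAS3 (2.68), TAS1B (1.17), TAS1A (0.87), TAS2 (0.87), TAS4 (0.85) and antisense RNA of DREB2A (-3.98), RD29A (-3.52) and RD29B (-2.86).

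Of the poly(A-) features that differed between genotypes under drought, protein-coding loci were mostly higher and unannotated regions mostly lower in the mutant. The 3 arrays of low detection were argued against as the whole cause, since 9277 features were called without them, against 12050, though 2850 without dried mutant array 3 alone and 1994 without array 2, which is not among them. A larger share of polyadenylated mRNA in the dried mutant's poly(A-) samples may contribute. The change followed the difference between poly(A+) and poly(A-) levels (Spearman rho 0.67, though also -0.41 without stress, where 50 features passed). With that trend removed from each array protein-coding loci went from 6093 up and 1805 down to 547 and 511 and regions from 49 and 1276 to 122 and 48. YLS8 went from 1.39 ± 0.28 to 0.37 ± 0.17, UBC21 only from 1.2 to 0.95 (adjusted p = 0.028) and TAS2 only from 7.72 to 7.45. Removal also takes out a real rise of untailed mRNA, so it cannot decide. Quantile scaling (7310 calls) decides nothing, as it may overcorrect groups whose levels truly differ. Genotype itself and each group's fixed place on the slide cannot be told apart and stay open.

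Antisense probes of drought genes that rose with drought in poly(A+) RNA may read copies of the spliced sense RNA made during labelling, as 85.7% of antisense probes across exon junctions (24 of 28) were detected in dried wild type, against 20.6% of those in introns (7 of 34) and 87.3% in exons (117 of 134). Products of RDR2 or RDR6 were argued against as the main source of this signal. The 120 raised probes had a median genotype change of -0.23 under drought (quartiles -0.36 and -0.03). In poly(A-) RNA 106 of them had -0.01. The values bear on RDR1 too, unless its mutation leaves it active, which was not tested. Smaller amounts hidden by such copies, and antisense RNA spliced like the sense strand or made by RNA polymerase II, stay open untested.

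Pseudogenes called higher in the mutant in poly(A+) RNA without stress were 82 of 505. Signal shared with a near-identical copy stays open. Of the 424 loci whose probe shares no 25 nucleotides with another 13% were higher, but 4.48% of 201 detected on every array and 1.8% of 3444 without a filter, so the filter decides that test. Linkage to the mutated genes was argued against, as 2.44% of the 82 lay within 200 genes of one. Silencing by small RNAs that need the polymerases is a candidate not tested, and genotype and position on the slide stay open.

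Other splits of the arrays were counted. Splits of 3 against 3 arrays number 10, too few for a share under 0.05. In each the real split alone (1 of 10) gave a count as large, and the highest other count was 72 for genotype without stress and 2 for genotype under drought in poly(A+) RNA, and 0 for drought in both genotypes and fractions and for genotype in poly(A-) RNA. Where same-numbered arrays share deviations 4 of the 10 splits part all 3 pairs, and the 72 came from such a split. For antisense loci in poly(A-) RNA the count was reached by 1 of 10 splits for drought in wild type (highest other 0), 1 of 10 for genotype under drought (0) and 10 of 10 for genotype without stress, whose real count was 0 in limma (1 at a raw p under 0.05). Of 100 splits for each interaction 2 reached the real count, the other giving 2832 against 55 in poly(A+) and 13381 against 7872 in poly(A-) RNA. It kept the labels of 1 treatment whole and swapped the rest, which turns the drought or genotype effect into the interaction. Splits that mixed both parts called at most 1, but hold group differences as spread. For antisense loci in the poly(A-) interaction the real count was 0, which all 100 splits must reach (highest other 1), so neither test decides anything. Between fractions 1 of 100 reached 43628 (highest other 37043). For the drought difference between fractions 9 of 100 reached 8662 (highest other 15450), so random splits were not excluded by that share. The other 8 kept 1 fraction's labels whole or swapped, a structure of the samples, and the 80 mixed splits called at most 4. For gene lists 1 of 100 reached 103 (highest other 96, median 67), so a preset-correlation pass alone is weak evidence.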

How the results depend on the processing

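The array median and detected-spot scalings, slides 2 and 3 alone, the poly(A-) fits without 3 arrays of low detection, the trend removal and the test of each antisense probe were chosen after the data were seen. Counts are features called, beside the value reported, and the cause of a change was not tested unless fewer arrays or features account for it. Signal over background limits which features were tested, with 56.3 to 90.9% of spots detected on poly(A-) arrays.

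Drought in wild type and in the mutant in poly(A+) RNA stayed within 1.5 times of 21705 and 22496 under all settings (20166 to 20882 and 20958 to 21502 with 1 array left out). Genotype without stress in poly(A+) RNA (1011) gave 670 with the filter on every array, 1648 with array weights and 667 with all 24 arrays (659 without unstressed wild-type array 3 to 1042). Genotype under drought (1703) gave 732 on slides 2 and 3 and 685 with all 24 arrays (939 to 1433 with 1 array left out). The interaction (55) gave 109 with the submitters' values, 100 with array weights, 6 on slides 2 and 3 and 35 with all 24 arrays (19 to 64 with 1 array left out).

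For poly(A-) RNA, drought in wild type (2707) gave 8070 with array weights, 1649 without the 3 arrays, 642 on slides 2 and 3, 6154 with all 24 arrays and 1746 with 6 (1663 to 3046 with 1 array left out). Drought in the mutant (20945) gave 13788 with the filter on every array and 13649 with the trend removed (15205 to 22375 with 1 array left out). Genotype without stress (50) gave 30 with the filter on every array, 1102 with array weights, 10 on slides 2 and 3, 253 with all 24 arrays and 19 with 6 (25 to 59 with 1 array left out). Genotype under drought (12050) gave 7310 with quantile scaling, 6304 with the submitters' values, 2628 on slides 2 and 3 and 2128 with the trend removed (1994 to 16920 with 1 array left out). The interaction (7872) gave 3861 with quantile scaling, 0 with the submitters' values, 5057 without a filter, 18402 with array weights, 0 without the 3 arrays, 0 on slides 2 and 3, 1 with the trend removed and 13921 with all 24 arrays. With the replicate as a block it gave 15414, and 14867 as a random block. Without 1 array it ran from 0 to 15650.

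Of 13 antisense loci in poly(A-) RNA, drought in wild type (1) gave 2 with quantile scaling, 2 with the submitters' values, 2 with the filter on every array, 3 with the mean over probes, 4 with array weights, 2 with array median scaling, 2 with the trend removed and 2 with 6 arrays. With the replicate as a block it gave 4, and 2 as a random block. Genotype under drought (1) gave 2 with quantile scaling, 0 with the submitters' values, 2 with the mean over probes, 2 with array weights, 2 without the 3 arrays, 0 on slides 2 and 3 and 0 with the trend removed. The 1 call was down, but up with array median scaling and with all 24 arrays, and 1 of the 2 was up with array weights. It gave 2 with the replicate as a block and 0 to 2 with 1 array left out, 0 without dried wild-type array 1 or 3 or dried mutant array 2 and 2 without dried mutant array 1. The interaction (0) gave 1 with quantile scaling, 1 with the filter on every array, 2 with the mean over probes, 1 with array weights, 1 with detected-spot scaling and 1 with the replicate as a fixed or random block (0 to 1 with 1 array left out, 1 without dried mutant array 1). Genotype without stress stayed at 0 in all 18 settings. With each of 197 antisense probes tested by itself the counts were 49, 25 and 17.

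Fractions (43628) gave 18421 with the filter on every array. The drought difference between fractions (8662) gave 3594 with quantile scaling, 4878 with the filter on every array, 13728 with array weights and 3358 on slides 2 and 3 (7184 to 9737 with 1 array left out). Of 252 tests of gene lists 103 passed, and 22 did so with an estimated correlation, 131 with fry and 102 with the replicate as a block. Between fractions the ABA metabolism list did not pass in camera (down, adjusted p = 0.68, and 0.65 to 0.81 with a block or an estimated correlation). It passed in fry (up, adjusted p = 1.4e-07, and 4.2e-06 with a block), a test against no change, not other genes.

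Of 343 values of named genes 261 kept direction and side of the threshold on slides 2 and 3, 295 with the submitters' values, 303 with quantile scaling, 320 with array median scaling, 322 with normexp, 339 with the replicate as a block and 335 to 343 with detected-spot scaling, array weights, the random block and the mean over probes. With the trend removed 103 of 141 did, and 172 of 201 without the 3 arrays. For genotype under drought in poly(A-) RNA 17 of 30 did with the trend removed. In the poly(A-) interaction only 6 of 30 did with the submitters' values, 7 of 30 with the trend removed and 155 of 360 with 1 array left out. Reversed were AT1G33840 in the poly(A+) interaction (-0.13, normexp) and YLS8 in the poly(A-) interaction (-0.06, trend removed). Between fractions AP1 reversed with normexp (0.29), the submitters' values (0.44) and detected-spot scaling (0.72), AG (-0.42) and SEP3 (-1.68) with quantile scaling, CA1 with the submitters' values (-0.03), and SEP3 (-1.22), CA1 (-1.61), AP3 (-0.07), KIN1 (-0.49), ERD10 (-1.24) and JAZ6 (-0.67) with array median scaling. In the drought difference TAS1B (-0.60), TAS1A (-0.75) and TAS2 (-0.26) reversed with quantile scaling. Scaling moved the median of all features by over 0.1 only in poly(A-) RNA and between fractions. It went from -0.16 to 0.03 (array median), -0.31 (detected spots), -0.05 (quantile) and -0.03 (submitters) for genotype under drought, and from -0.34 to -0.05, -0.56, -0.14 and -0.10 for the interaction. The replicate as a block changed no call of a named gene or list other than those given with the results.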

Other observations

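Drying of wild type raised 6 and lowered 73 of 146 poly(A+) snoRNA and snRNA features, but 3 and 0 of 6 annotated snRNAs. Of 131 tRNA features 27 rose and 64 fell, beside 40.2% of protein-coding genes, a difference not tested. In the mutant the 146 had 6 and 83, tRNAs 26 and 52. Both stood higher in poly(A-) RNA (149 of 151 and 189 of 190), so carry-over from it stays open. There limma called 0 of 151 (median -0.10) and 3 down of 190 tRNAs (median 0.28) in dried wild type.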
